A study of Mus musculus with 2 samples.

How the data were processed

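Gene expression was measured in mouse embryonic fibroblasts (MEFs), primary connective-tissue cells grown from embryos, of the reciprocal genotypes MatDup.dist7 and PatDup.dist7. Both cultures came from embryos at 13.5 days post coitum, per the labels. Total RNA was extracted with RNA-Bee, treated to remove DNA, labelled with biotin by the Affymetrix whole-transcript sense-target protocol and hybridised to 1 array per genotype, per the labels' protocols. There was thus 1 sample per group and no replicate.

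The deposited table holds 1 intensity per probe set and array on a linear scale. The submitters' processing notes name Affymetrix Expression Console. The background correction, summarisation and normalisation methods are not given in the sources used here. All 35557 values per array were above 0. The sorted values differed between the arrays, so the columns were not identical in distribution. The median intensity was 68.6 on the MatDup.dist7 array and 64.2 on the PatDup.dist7 array. On these arrays 4.78% and 5.03% of the probe sets, respectively, had a value under 1. A value under 1 was not read as absence of the transcript. Of 306 genes for ribosomal, proteasome, respiratory complex I, translation, RNA polymerase II and chaperone proteins, a set chosen by symbol after the values were seen, 1 had a value under 1 in an array.

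Probe sets were named through the platform annotation. Of the 35557 probe sets, 21789 had 1 gene symbol, 1621 had several and 12147 had none. Only those with 1 symbol were used. The gene identifiers of 21698 of them were found in the reference gene table of assembly GRCm38.p6, which gave the current symbol, the chromosome and the order of genes along it. The build behind the array annotation is not given in the sources used here, so no coordinates are printed. Older symbols in the gene lists were matched through that table's synonyms.

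The design had assumed values on a log2 scale. As the deposited intensities were linear, log2(intensity + 16) was computed, and the probe sets of a gene were averaged, giving 19938 genes. The pseudocount of 16 was set after the range of the values, but not their differences, had been seen. All differences are MatDup.dist7 minus PatDup.dist7 on this scale, which understates the change of genes with low signal. The median difference over all genes was 0.02. Genome-wide and chromosome counts used a 2-fold rule among the 12733 genes whose higher value lay above the 50th percentile of all probe sets, an intensity of 66.4. Counts within gene lists and families used the 2-fold rule on all measured members, including those under this filter.

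With 1 array per genotype no test between genotypes can be made, and no p-value is given. For genes with several probe sets, the standard deviation of the log2 difference between probe sets of the same gene was 0.40 (1722 probe sets of 642 genes above the filter). This describes the agreement of probe sets within the arrays and holds no variation between cultures or embryos. Each fixed gene list was described by its median log2 difference and by the percentile of that median among 10000 random lists of the same size, drawn with replacement from 20 bins of mean level. Chromosomes were described in the same way among the genes above the filter. Of the 32 lists apart from the sex-linked check genes, 1.6 would be placed outside the central 95% of random lists if genes varied independently. Genes of 1 list can vary together, and some lists share members, so a larger number does not by itself show an excess over chance.

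The lists, the comparisons, the 2-fold rule, the first set of alternatives and the rule for naming genes were fixed before the data were examined. The rule named every measured member of the chromosome 7 imprinted lists and of the sex-linked list, the 15 genes with the largest difference in each direction above the filter (leaving out symbols of the Gm and Rik kind), and in each other list up to 4 members at least 2-fold apart with the largest difference, or the largest one where none was. Other genes given as examples from the lists were chosen after their values were seen. The lists covered imprinted genes by position and parental origin, markers of fibroblasts, skeletal and smooth muscle, macrophages, endothelium, neural and glial cells, epithelium, cartilage and bone, adipocytes, erythroid cells and trophoblast or germ cells, Hox and other regional genes, and genes of the cell cycle, the p53 response and senescence, the insulin-like growth factor axis, the interferon response, inflammatory cytokines, cholesterol synthesis, hypoxia, the unfolded protein response, the matrix, developmental signalling and epigenetic regulation. Dcn was in the fibroblast list and, like Grb10 and Igf2r of the growth factor axis, among the imprinted genes of other chromosomes.

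The calculations were tested on simulated arrays with real levels and a noise of 0.4 (standard deviation of the log2 difference). Over 12392 simulated genes above the filter, the 2-fold rule recovered 88.0% of genes changed 3-fold, 52.0% of those changed 2-fold and 12.0% of those changed 1.5-fold, and it picked 1.44% of unchanged genes. Of 200 simulated unchanged lists, 5.0% fell outside the central 95%, and of 100 lists shifted by 0.4, 98.0% did. The noise was independent between probe sets and held no variation between cultures. List members were drawn at random, and the changed genes were drawn from those above the median level. These rates thus check the calculations and are not error rates of the measured arrays or of lists of related genes.

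The alternatives were quantile normalisation of the arrays, centring on the median difference, removal of a loess trend (span 0.3), the filter switched on or off, the probe set with the highest mean level, a 3-fold rule and a floor at the 25th percentile. Pseudocounts of 1 and 64, leaving out probe sets under 1, and leaving out genes of chromosomes X and Y were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.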

Results

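Transcript levels were compared between MatDup.dist7 and PatDup.dist7 MEFs. In MatDup.dist7 embryos both copies of the distal part of chromosome 7 are of maternal origin, and in PatDup.dist7 embryos both are of paternal origin. Genes expressed from 1 parental copy in this segment are thus expected from both copies or from neither, while the copy number of the segment is equal. The comparison addresses which genes of the chromosome differ by parental origin. Each genotype was measured on 1 array, and the log2 levels of the 19938 genes correlated across genes with r = 0.936 (Spearman 0.924), genes not being independent replicates. Without replicate arrays, no difference below was tested against variation between cultures, and the number of arrays limits the precision of every value.

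Cdkn1c and Igf2, both in the distal imprinted cluster of chromosome 7, showed the largest differences among the 12733 genes above the signal filter on the log2(intensity + 16) scale, in opposite directions. With a pseudocount of 1, Cdkn1c kept rank 1 and Igf2 ranked 5, behind Endov, Sfn and Cbr2. Cdkn1c, a maternally expressed inhibitor of cyclin-dependent kinases, had an intensity of 1109 in MatDup.dist7 and 0.0132 in PatDup.dist7, a log2 difference of 6.13. Igf2, a paternally expressed fetal growth factor, had an intensity of 7.48 in MatDup.dist7 and 1013 in PatDup.dist7, a log2 difference of -5.45. On the log2(intensity + 16) scale these are 70.3-fold and 43.8-fold differences. The size depends on the pseudocount, since the lower value lies near the bottom of the scale: with pseudocounts of 64 and 1 the log2 difference was 4.20 and 10.1 for Cdkn1c and -3.91 and -6.90 for Igf2. The low Cdkn1c value comes from 1 probe set and does not by itself show absence of the transcript.

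The other measured genes of the distal cluster that are known as maternally expressed in the embryo differed little. H19, also in this list, had no value here. The same held for Igf2os and Kcnq1ot1 of the distal paternal list and for Snrpn, Snurf, Snhg14 and Ube3a of the central lists. Phlda2, a growth-restraining gene of the placenta, had intensities of 1416 in MatDup.dist7 and 1272 in PatDup.dist7 (log2 difference 0.15). Kcnq1, a potassium channel gene, had 213 and 155 (0.43), and Slc22a18, a transporter gene, had 72.7 and 50.6 (0.41). All 4 measured members of the distal list, with Cdkn1c, were higher in MatDup.dist7, 1 of them by at least 2-fold. Their median difference was 0.42, the 94.7th percentile of random lists.

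The breakpoint of the duplicated segment is not given in the sources used here, so no gene was assigned to the segment. Of 10 distal genes reported as maternally expressed mainly in placenta, 1 was at least 2-fold higher in MatDup.dist7 and 9 lay within 2-fold. The former was Th, which encodes tyrosine hydroxylase, the rate-limiting enzyme of catecholamine synthesis, with 75.6 in MatDup.dist7 against 2.72 in PatDup.dist7 (log2 difference 2.29, or 4.37 and 1.06 with pseudocounts of 1 and 64). Among the others, Ano1 and Ampd3 had differences of 0.40 and 0.21, Tssc4 of 0.02, Cd81 of -0.15, Tspan32 of -0.27, Ascl2 of -0.36, Nap1l4 of -0.44, Osbpl5 of -0.53 and Dhcr7 of -0.70. The list median was -0.21 (14.4th percentile) and its mean 0.05, so the median and mean differed in sign. Of the 3 measured paternally expressed distal genes, Igf2 was the one beyond 2-fold. Inpp5f, which has a paternally expressed isoform not resolved here, stood at 65.6 in MatDup.dist7 and 111 in PatDup.dist7 (-0.64), and Ins2, an insulin gene, at 63.2 and 52.5 (0.21). Their median was -0.64, at the 2.54th percentile, and 4 of 10 alternatives placed it outside the central 95%. Among the 4 was the signal filter, which left only Igf2 and Inpp5f. Ampd3 and Inpp5f stand at places 732 and 886 of the 1046 genes in order along the chromosome and Igf2 at 1016, and whether the former lie in the segment was not established.

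Imprinted genes elsewhere on chromosome 7 lay within 2-fold. In the central cluster, the paternally expressed Ndn, which encodes necdin, had 1264 in MatDup.dist7 and 1023 in PatDup.dist7 (log2 difference 0.30). Magel2 had 140 and 128 (0.11), Peg12 had 66.5 and 85.2 (-0.29), and the weakly detected Mkrn3 had 2.03 and 17.7 (-0.90). Atp10a, reported as maternally expressed, had 150 and 69.5 (0.96, the 96.7th percentile of single genes drawn at random, or the 97.7th with a pseudocount of 64). Its difference passed 2-fold with a pseudocount of 1 (1.10) and with a floor at the 25th percentile (1.11). In the proximal cluster, the difference was -0.88 for Peg3 (102 and 202), -0.04 for Usp29 and 0.69 for Zim1. The median was -0.09 for the 4 central paternal genes (36.7th percentile) and -0.04 for the 3 proximal genes (36.8th percentile). Over all 25 measured imprinted genes of chromosome 7, 3 differed by at least 2-fold and 22 did not.

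**Figure D1:**
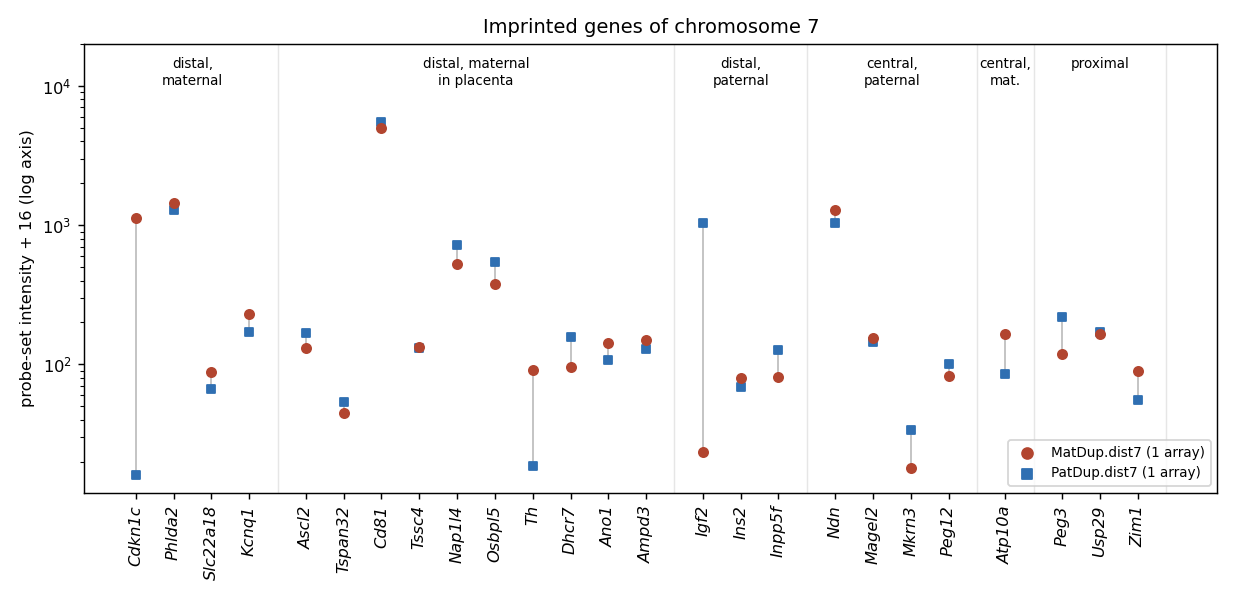
Probe-set intensity plus 16, on a log axis, of the 25 measured members of the chromosome 7 imprinted lists, grouped by position and expressed parental copy. Circles are the single MatDup.dist7 array and squares the single PatDup.dist7 array, joined per gene. Cdkn1c, Igf2 and Th are far apart, whereas Phlda2, Cd81 and Ndn nearly coincide.

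Along chromosome 7 the large differences at the distal end were isolated among genes above the signal filter. A stretch of 30 genes above this filter reached from 10 genes before Igf2 to 10 genes after Cdkn1c. Of its other 28 genes, Th was the only one to differ by at least 2-fold, and their median absolute difference was 0.37. Measured genes under the filter were not counted. Tumour necrosis factor receptor genes of the stretch, Tnfrsf22 and Tnfrsf23, had differences of -0.32 and -0.29, and the lysosomal protease gene Ctsd of -0.38; these were chosen as neighbours after their values were seen. Over the whole chromosome, 48 of 1046 genes (4.59%) differed by at least 2-fold, compared with 609 of 11687 genes (5.21%) on all other chromosomes. Without genes of X and Y the latter was 575 of 11303 genes (5.09%). Both of these counts include some genes without an assigned chromosome. The share on chromosome 7 lay at the 3.37th percentile of random lists matched on level. Which share was larger depended on the setting. On chromosome 7 and the other chromosomes, respectively, the shares were 9.19% and 8.63% with a pseudocount of 1, 9.19% and 8.82% with a floor at the 25th percentile, 7.73% and 7.63% without the signal filter, 1.43% and 1.16% with a 3-fold rule, and 1.24% and 1.36% with a pseudocount of 64. The median difference of chromosome 7 genes was 0.08, above all 10000 random lists, whose central 95% ran from -0.04 to 0.04. This was not peculiar to chromosome 7. The median was 0.06 on chromosome 11 and -0.10 on chromosome 13 (0.12th percentile), and those of chromosomes 1, 3, 16, 17, 18 and 19 also lay outside the central 95%.

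**Figure D2:**
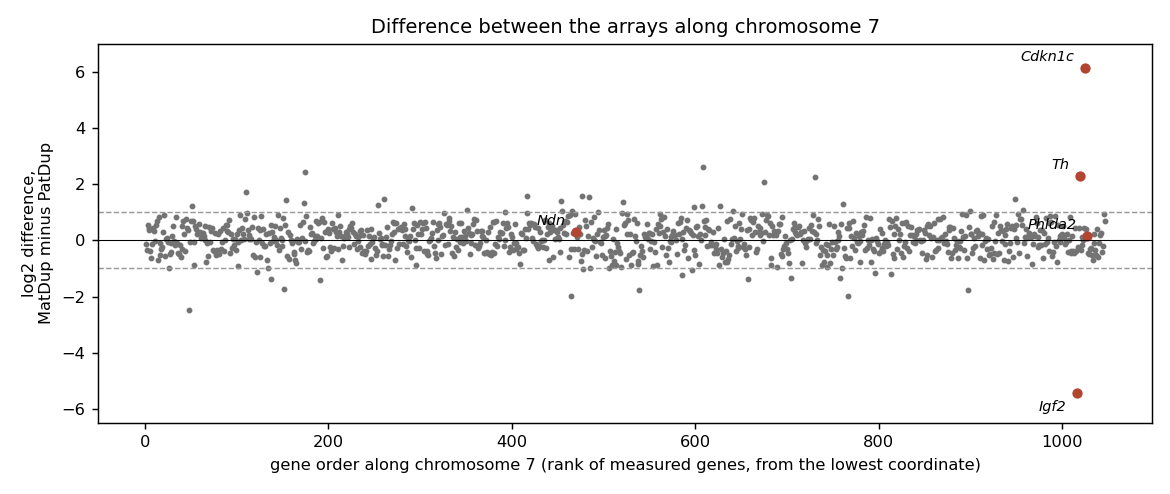
Log2 difference (MatDup.dist7 minus PatDup.dist7) of the 1046 chromosome 7 genes above the filter, in gene order; dashed lines mark 2-fold. Cdkn1c (6.13), Th (2.29) and Igf2 (-5.45) stand out at the distal end beside neighbours such as Phlda2 (0.15), and Ndn of the central cluster lies near 0.

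Genes listed as imprinted on other chromosomes included members higher in either genotype. Whether these genes are imprinted in the cultured cells was not measured. Of 16 measured paternally expressed genes, 2 were at least 2-fold higher in MatDup.dist7 and 2 in PatDup.dist7. Slc38a4, an amino acid transporter gene, had 171 in MatDup.dist7 against 8.97 (log2 difference 2.91), and Peg10, a retrotransposon-derived gene, 1093 against 430 (1.31). Airn, a non-coding RNA of the Igf2r locus, had 25.5 against 89.4 (-1.35), and Mest had 105 against 252 (-1.15). The median was -0.07 (28.1th percentile) and the mean 0.11. Of 22 genes listed as maternally expressed, 3 were at least 2-fold higher in MatDup.dist7 and 1 in PatDup.dist7, the latter being Dcn, which encodes the matrix proteoglycan decorin (142 and 592, log2 difference -1.95). The 3 higher ones, Phactr2, Ppp1r9a and Rian, had PatDup.dist7 values under 1 and MatDup.dist7 values of 31.8, 26.3 and 17.8, and none of them lay above the signal filter. The list median of 0.27 (97.8th percentile) lay outside the central 95% of random lists, as it did under 6 of 10 alternatives. Among the 6 was centring, which cannot change a percentile. It was 0.01 (59.7th percentile) when probe sets under 1 were left out.

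Across the genome, 349 genes were at least 2-fold higher in MatDup.dist7 and 308 in PatDup.dist7, which is 5.16% of the genes above the filter, and 39 and 25 genes, respectively, were at least 4-fold higher. These counts depend on how low signals are treated: they were 604 and 499 with a pseudocount of 1 and 92 and 80 with a pseudocount of 64. Which count was larger depended on the scaling, with 285 and 367 after quantile normalisation of the arrays. The arrays also differed in sex-linked transcripts. The Y-linked Eif2s3y, Uty and Kdm5d had 112, 77.9 and 122 in MatDup.dist7 against 6.44, 2.61 and 22.9 in PatDup.dist7, while Xist, the RNA of the inactive X chromosome, was listed at 0.00166 in MatDup.dist7 and 91.2 in PatDup.dist7. The median of these 4 genes was 2.08, above all random lists. The genotypes therefore differed in the sex-linked transcripts of the cultures as well, so an effect of sex is confounded with genotype for autosomal genes too. Leaving out genes of chromosomes X and Y (counts of 323 and 300) does not remove this.

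Besides Cdkn1c, the 15 genes with the largest excess in MatDup.dist7 included Endov, a nucleic acid repair endonuclease gene (564 and 0.0898, log2 difference 5.17), and Sfn, the epithelial stratifin gene, whose probe sets stood at 516 against 0.0143 and 280 against 4.02 (mean difference 4.47). They also included Ppbp, a platelet chemokine gene (3.57), Stmn2, a neuronal microtubule regulator (755 and 73.7, 3.10), the vesicle-traffic gene Rab3b (2.76), Mogat2, a triglyceride synthesis gene on chromosome 7 (2.61), Clca3a2 (2.58) and Fgf13 (2.57). Cbr2, Adamts20 and Ppef2 had MatDup.dist7 values of 140, 95.3 and 71.7 and PatDup.dist7 values under 1. In PatDup.dist7, the 15 genes with the largest excess besides Igf2 included Col10a1, the collagen of hypertrophic cartilage (43.7 and 595, log2 difference -3.35), Plekhg1 (-2.52), Cd59a, a complement inhibitor gene (-2.43), Gfra1, a receptor gene for glial-derived neurotrophic factor (-2.39), Gsta4, a glutathione transferase gene (107 and 596, -2.32), and Tnn, which encodes the matrix protein tenascin N (-2.28). Prss12, Unc45bos and the chromosome 7 gene Zfp28 had PatDup.dist7 values of 104, 72.9 and 74.2 and, like Fam107a, MatDup.dist7 values under 1. Where the lower value was under 1, as also for Endov, the size of the difference and the place among the 15 depend on the pseudocount. The granule protease genes Gzme (38.9 and 344), Gzmd (21.4 and 162) and Mcpt4 (20.2 and 183) were also among these 15, with differences of -2.71, -2.25 and -2.46. They belong to families of closely similar sequence, so signal from related genes at their probe sets is not excluded.

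Hox genes, which specify position along the body axis, were higher in MatDup.dist7 as a group. Of 37 measured, 27 had a positive difference, and 5 were at least 2-fold higher in MatDup.dist7, 4 of them above the signal filter, and none in PatDup.dist7. Hoxa5 had 469 in MatDup.dist7 and 55.8 in PatDup.dist7 (log2 difference 2.76), Hoxa3 differed by 1.96, Hoxa4 had 68.0 and 8.48 (1.78) and Hoxc5 had 184 and 45.4 (1.71). The median of the list was 0.51, above all 10000 random lists. Other regional transcription factors went both ways: Pax1 (46.7 and 0.0074) and Nkx3-2 (1.27) were higher in MatDup.dist7, and Emx2 (5.91 and 56.4) and Pax3 (-1.37) in PatDup.dist7, all 4 under the signal filter. Shox2 (43.2 and 114, -1.13) was the only regional gene above it to differ by at least 2-fold. The median of the 29 regional genes was 0.16 (81.3th percentile) and the mean -0.0020.

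Cartilage and bone markers were also higher in MatDup.dist7, with 10 of 11 differences positive and a median of 0.70 (99.9th percentile). Col2a1, the main collagen of cartilage, had 599 and 141 (1.97). Comp, a cartilage matrix protein gene, had 54.9 and 4.44 (1.80) but lay under the signal filter, and 6 of the 11 markers lay above it. Col10a1, outside the list, went the other way. Cell-cycle genes had a median of 0.40 (99.9th percentile), with 19 of 25 differences positive and none reaching 2-fold; the mitotic kinase gene Plk1 had 427 and 237 (0.81). The 6 negative ones were Mcm2 (-0.17), Mcm3 (-0.50), Mcm4 (-0.03), E2f1 (-0.56), Bub1 (-0.48) and Mki67 (-0.08). Other replication genes, among them Mcm5 (0.38), Mcm6 (0.55) and Rrm2 (0.45), were positive. Among 18 inflammatory cytokine genes, 5 were at least 2-fold higher in MatDup.dist7, 3 of them above the signal filter, and none in PatDup.dist7, with a median of 0.33 (98.6th percentile). The chemokine gene Cxcl12 had 1320 and 376 (1.77), Ccl20 had 69.5 and 17.4 (1.36), the growth factor gene Csf2 had 61.0 and 18.8 (1.14, under the signal filter) and Ccl5 had 118 and 46.5 (1.10). The cytokine list fell inside the central 95% of random lists when the signal filter was applied (96.1th percentile) and with a pseudocount of 1 (97.4th percentile).

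Extracellular matrix genes were higher in PatDup.dist7. Of 29 measured, 24 had a negative difference, 3 were at least 2-fold higher in PatDup.dist7 and 1 in MatDup.dist7, and the median of -0.51 lay below all 10000 random lists. The matrix metalloproteinase genes Mmp13 (53.3 and 256) and Mmp3 (89.1 and 342) had differences of -1.97 and -1.77, Col12a1 of -1.10 (1926 and 4151), and Tnxb of 1.01. Fibroblast markers had a median of -0.39 (0.33th percentile), with 11 of 14 differences negative. Postn, encoding the matrix protein periostin, had 520 and 1788 (-1.75), while Vim, the mesenchymal intermediate filament gene, had 11913 and 11542 (0.05). The fibroblast list lay at the 2.63th percentile with a floor at the 25th percentile of the signals.

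The insulin-like growth factor axis, listed without Igf2, was higher in PatDup.dist7, with 12 of 17 differences negative and a median of -0.43 (0.05th percentile). Igfbp3, which encodes a circulating binding protein for these growth factors, had 228 and 953 (-1.99), the serine protease gene Htra1 on chromosome 7 had 344 and 1221 (-1.78), and Igfbp5 had 56.6 and 187 (-1.48). Igf1r, the receptor gene, had 585 and 537 (0.12). Genes of the p53 and senescence list had a median of -0.41 (0.24th percentile), with 9 of 12 differences negative. Cdkn2b, another inhibitor of cyclin-dependent kinases, had 1026 and 3659 (-1.82), whereas the p53 target Ccng1 had 6283 and 7236 (-0.20). Without genes of chromosomes X and Y the latter list lay at the 2.89th percentile.

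Markers of macrophages, which can accompany primary fibroblast cultures, had a median of -0.43 (0.04th percentile). Of 15 markers, 10 differences were negative, and Mrc1, the mannose receptor gene, was at least 2-fold higher in PatDup.dist7 (31.7 and 103, -1.32). The markers did not move together: Adgre1, which encodes F4/80, had 548 and 273 (0.96), and Csf1r had 855 and 746 (0.19). The epithelial list had 10 of 11 positive differences and a median of 0.39 (92.7th percentile, or 98.4th with a pseudocount of 64), with Krt19 at 152 and 18.8 (2.27) and Krt5 differing by 1.16. Krt5 lay under the signal filter.

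**Figure D3:**
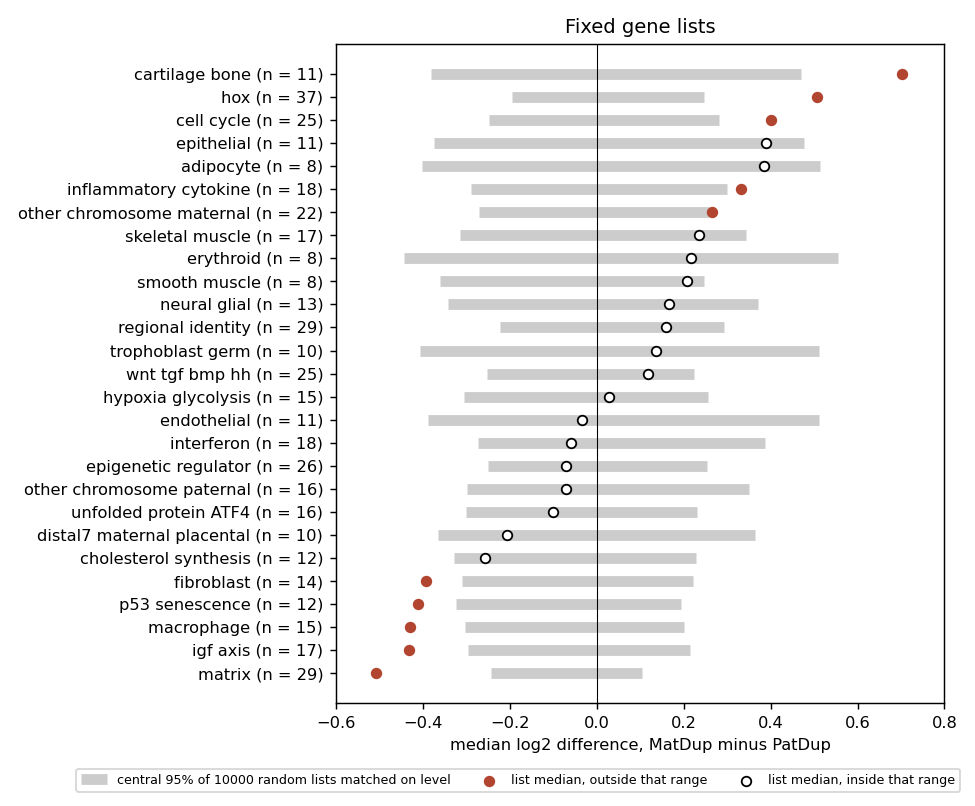
Median log2 difference (MatDup.dist7 minus PatDup.dist7) of each fixed gene list with at least 5 measured genes; bars show the central 95% of 10000 random lists matched on signal level, and filled points lie outside it. Cartilage (0.70) and Hox genes (0.51) lie to the right, and matrix (-0.51) and insulin-like growth factor axis genes (-0.43) to the left.

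Lists for the remaining cell types and pathways lay inside the central 95% of random lists, the adipocyte list going outside with a floor at the 25th percentile of the signals (98.1th percentile). The median was 0.23 for skeletal muscle (90.4th percentile), where Myh8 (59.5 and 2.31) and Chrna1 (26.2 and 3.37) were at least 2-fold higher in MatDup.dist7 but under the signal filter, and 0.21 for smooth muscle (95.7th percentile; mean -0.0047), where Myh11 was higher in PatDup.dist7 (61.9 and 199). It was 0.39 for adipocyte (90.9th percentile; Lpl 0.73), 0.22 for erythroid (68.7th percentile; Ermap 0.68), 0.17 for neural and glial (76.7th percentile), -0.03 for endothelial (30.0th percentile; Esam 22.6 and 0.00156) and 0.14 for trophoblast and germ cell markers (60.1th percentile; mean -0.07; Tpbpa -1.01). Of the pathway lists, developmental signalling genes had a median of 0.12 and a mean of -0.19 (86.8th percentile), with Dkk2 (38.5 and 176) and Lef1 (60.0 and 211), genes of the Wnt pathway, at least 2-fold higher in PatDup.dist7 and Axin2, a Wnt target, listed at 0.0028 in MatDup.dist7 and 54.4 in PatDup.dist7. The median was -0.07 for epigenetic regulators (30.2th percentile), among which Uhrf1, a maintenance factor of DNA methylation, had 122 and 35.4 (1.42), Zfp57, a protector of imprints, 70.2 and 26.2 (1.03), and Tet2, a methylcytosine oxidase gene, 44.9 and 108 (-1.02). It was 0.03 for hypoxia and glycolysis (68.96th percentile), where Adm, the adrenomedullin gene on chromosome 7, had 370 and 64.4 (2.26), and -0.10 for the unfolded protein response (36.6th percentile), where the stress gene Ddit3 had 90.9 and 213 (-1.10). Interferon-responsive genes had a median of -0.06 and a mean of 0.02 (23.7th percentile; Ifit1 -1.14, Mx1 1.07), and cholesterol synthesis genes a median of -0.26 (8.81th percentile; Nsdhl -0.76). Of the genes named from these lists, Esam, Tpbpa, Axin2, Ifit1 and Mx1 also lay under the signal filter. In all, 10 of the 32 lists lay outside the central 95%, 5 in each direction, compared with 1.6 if genes varied independently. As genes of 1 list can vary together and some lists share members, this does not show an excess over chance.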

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

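Pseudocounts of 1 and 64, leaving out probe sets under 1 and leaving out genes of chromosomes X and Y were chosen after seeing the data; the others were planned. No paired analysis was possible because each genotype had 1 array, and no array could be left out. The counts of genes at least 2-fold higher in MatDup.dist7 and PatDup.dist7 (349 and 308) were 891 and 631 without the signal filter, 84 and 66 at 3-fold, 616 and 510 with a floor at the 25th percentile, 604 and 499 with a pseudocount of 1 and 92 and 80 with a pseudocount of 64. They were 285 and 367 after quantile normalisation and 281 and 368 after removal of the loess trend, which turned the larger count from MatDup.dist7 to PatDup.dist7, as centring did (326 and 331). The share of genes beyond 2-fold on chromosome 7 (4.59%) was 7.73% without the filter, 1.43% at 3-fold, 9.19% with the floor and with a pseudocount of 1, and 1.24% with a pseudocount of 64. The share on all other chromosomes (5.21%) was 1.16%, 8.82%, 8.63% and 1.36% under the last 4 of these. Of 329 alternative list medians, none of those outside the central 95% reversed and 11 moved by more than the spread of random lists. With the filter, the median was -3.05 for the distal paternal genes, 0.0771 for maternally expressed genes of other chromosomes and -0.15 for neural markers. The first of these rests on Igf2 and Inpp5f alone, as Ins2 lay under the filter, and is thus largely the difference of Igf2. It was -0.40 for matrix genes without the loess trend, -0.12 for hypoxia genes with the highest probe set, 0.0105 for maternally expressed genes of other chromosomes without probe sets under 1 and -0.11 for trophoblast and germ markers without genes of X and Y. For cartilage it was 0.96 with a pseudocount of 1 and 0.42 with 64, and for the sex-linked genes 3.15 and 1.10. The Hox, cartilage, cell-cycle, insulin-like growth factor, matrix and macrophage lists stayed outside the central 95% under each of the 10 alternatives run for them. The maternally expressed genes of other chromosomes did so under 6 of 10. Centring shifts all genes alike and cannot change a percentile. Choosing the highest probe set changes little, as most list members had 1 probe set. The 10 alternatives are therefore not 10 separate checks. Of 932 alternative values of the 106 named genes, none of those beyond 2-fold changed sign and 150 moved by more than the spread between probe sets, 148 of them under the floor or another pseudocount. Those settings change low values by construction, and variation between cultures was not measured. For a gene with 1 probe set, a floor, another pseudocount or leaving out genes cannot reverse a sign. Most of the unchanged signs were thus fixed in advance and say little about stability. Cdkn1c has no value when probe sets under 1 are left out, as its only probe set is among them.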

Other observations

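The gene families and the tests of explanations in this part were chosen after the results were seen, except the removal of the loess trend, which was planned. The 22 gene families were grouped by their symbols, and some share members with the fixed lists. Families not mentioned below lay inside the central 95% of random lists. The medians and percentiles given for families and chromosomes are for the deposited scale; the medians kept their sign but not their size after quantile normalisation, centring and removal of the loess trend. The median of cytoplasmic ribosomal proteins went from 0.08 to 0.13 with quantile normalisation and 0.17 without the trend, that of olfactory receptors from 0.18 to 0.10 without the trend and that of chromosome 11 from 0.06 to 0.03 with quantile normalisation. Collagen genes as a family were lower in MatDup.dist7, with 6 of 44 at least 2-fold higher in PatDup.dist7 (4 of them above the signal filter), 1 in MatDup.dist7 and a median log2 difference of -0.38 (0.01th percentile of 10000 random lists matched on level). Of the 44, 17 were in the fixed lists, and the median of the other 27 was -0.23 (2.79th percentile), inside the central 95%. Beside Col10a1 and Col12a1, the basement membrane collagen genes Col18a1 (48.7 and 150, log2 difference -1.36) and Col4a4 (0.0192 and 38.6, under the signal filter) went this way, while Col2a1 went the other way. Of 15 granzyme and mast cell protease genes, 5 were at least 2-fold higher in PatDup.dist7 and none in MatDup.dist7. Besides Gzme, Gzmd and Mcpt4 these were Gzmg (9.39 and 72.2) and Mcpt8 (147 and 500), all on chromosome 14.

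Lysosomal cathepsins had a median of -0.35 (0.88th percentile) over 17 genes, and mitochondrial ribosomal proteins a median of -0.22 (0.10th percentile) over 77 genes, of which 1, under the signal filter, reached 2-fold. Cytoplasmic ribosomal proteins had a median of 0.08 (99.7th percentile) over 57 genes, none of which reached 2-fold. Small nucleolar RNAs had a median of 0.26 (99.1th percentile) over 51 genes. Olfactory receptor genes, of which 172 of 1027 lay above the filter, had a median of 0.18 (99.9th percentile). Keratin genes included Krt4 (58.0 and 0.0036) beside Krt19, with 8 of 48 at least 2-fold higher in MatDup.dist7 and 2 in PatDup.dist7. Of these, 1 in each direction lay above the signal filter. Mmp12, a macrophage elastase gene, had 75.9 and 325 (log2 difference -1.89), but the 22 matrix metalloproteinase genes had a median of -0.04 (36.5th percentile). The 29 genes of the replication family, 5 of which were in the fixed lists, had a median of -0.01 (35.6th percentile). A difference between this family and the cell-cycle list was not tested. Among 5637 probe sets above the filter without a single gene symbol, 147 were at least 2-fold higher in MatDup.dist7 and 123 in PatDup.dist7.

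Phlda2, Slc22a18 and Kcnq1 differed by less than 2-fold although Cdkn1c, a neighbour with the same reported parental origin, had the largest difference on the log2(intensity + 16) scale. Signal at the ceiling of the array is argued against, because the highest of the 3 genes' intensities lay at the 96.5th percentile of its array. Cells with a maternal copy mixed into the PatDup.dist7 culture are argued against as well: at the median PatDup.dist7 to MatDup.dist7 intensity ratio of the 3 genes, 0.724, they would bring Cdkn1c to 804, but it was listed under 1 (a ratio of 1.19e-05, read only as far below 0.724), and none of the 2402 other probe sets at or above 804 in MatDup.dist7 was under 1 in PatDup.dist7. Signal of other transcripts at these probe sets remains open, since probe sequences were not used here: the PatDup.dist7 intensity was 1272 for Phlda2 and 155 for Kcnq1, against an array median of 64.2, while Slc22a18 was weak in both arrays (72.7 and 50.6). Expression of these genes from paternal copies in cultured fibroblasts is a candidate explanation that was not tested.

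Hox and cartilage genes were higher in MatDup.dist7, and fibroblast, matrix and macrophage genes in PatDup.dist7. A lower share of fibroblasts in the MatDup.dist7 culture remains open. The cartilage median exceeded the macrophage median by 1.13, with a standard deviation of 0.26 for the difference of random lists. Both lists were chosen because they lay at opposite ends of this pattern, and a lower share need not raise all other cell types alike. The gap therefore cannot decide this. A trend with signal level common to all genes is argued against, since the random lists were already matched on level. After the trend was removed, the Hox median was 0.55 and the matrix median -0.40, both still outside the random lists. Given that matching, the removal was not a separate test. Cells from different body regions or embryos may account for part of the pattern. The median of the 17 Hox genes of paralog groups 1 to 6 was 0.72. That of the 16 genes of groups 9 to 13 was 0.16, a gap of 0.56. With 1 culture per genotype, which also differed in sex-linked transcripts, this and an effect of the genotype cannot be told apart.

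Genes of chromosome 7 as a whole had a median difference of 0.08, above random lists. The most distal genes did not carry this shift alone: the median was 0.11 over the first 5 of 10 equal parts of the chromosome by gene order (99.9th percentile) and 0.01 over the last 3 parts (73.7th percentile), which taken singly had -0.07, 0.07 and 0.09 (93.7th percentile for the last). The chromosome stayed at the 99.96th percentile of 10000 lists from other autosomes matched on level and local gene density. The densest regions elsewhere had a median of 0.05 and the sparsest of -0.02. Such lists draw genes independently, and several other chromosomes also lay outside random lists drawn in this way. The percentile therefore cannot decide whether gene density accounts for the shift. Base composition of the probes was not tested, and without olfactory receptor genes the median was 0.07. A biological explanation was not tested.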
